A study of Homo sapiens with 4 samples.

How the data were processed

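RNA was measured in DLD-1 cells, a human colorectal adenocarcinoma line, after transfection with siRNA against FBL (siFBL) or against LacZ, a bacterial gene that human cells lack (siLacZ, the control). Per the labels' protocols, cells were transfected with 50 nM siRNA, the transfection lasted 6 h and RNA was taken at 72 h. Libraries were made from 1.2 µg RNA with a SMARTER mRNA-seq kit, per the labels' protocols, and the labels name the RNA as polyA RNA. The deposited values are raw counts per gene, 1 table per sample, with numeric gene identifiers and no normalization. Per the submitters' processing notes the genome build was hg38. The aligner, the counting tool, the annotation, the treatment of reads that match several places and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies (ribosomal proteins, histones, keratins, heat shock proteins) are uncertain to that extent.

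The 4 tables held the same 28395 gene identifiers, of which 27745 matched a RefSeq gene table of assembly GRCh38.p14. Symbols and coordinates were taken from that table. The total count was 20635674 in the table of siLacZ replicate 13, 20631862 in that of siLacZ replicate 15, 16712693 in siFBL replicate 13 and 20169388 in siFBL replicate 15. Before any test the tables were compared pairwise. The table of siLacZ replicate 13 carried a column heading that names replicate 15, and its values equalled those of siLacZ replicate 15 in 27858 of 28395 genes. The other 537 differed by -4 to 21 counts and fell into 64 runs of neighbouring identifiers. Among genes with a mean of at least 100 counts, 96.6% were exactly equal, where independent counting of the same RNA would give 1.17%. A chi-square over those genes came to 0.00307 per degree of freedom, against 28.8 for the siFBL pair. The siLacZ tables differed by less than the sampling noise and were counted as 1 library, with the rounded mean of both. The design fixed before the data were examined had assumed 4 libraries. The comparison was therefore made on 3 libraries, 1 siLacZ and 2 siFBL, with 1 residual degree of freedom.

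Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, libraries were scaled with TMM, and siFBL was compared with siLacZ by the quasi-likelihood F test with robust dispersion and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.138. The standard error of a log2 fold change was computed from the estimate and its F value. The spread comes from the pair of siFBL libraries and the genes' shared trend, and the lone siLacZ library is assumed to vary like them. No source says whether replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are given as CPM after TMM scaling, as computed here.

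Gene groups were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, over lists with at least 5 tested members, with adjustment over the lists. The 40 lists, with 1271 genes, were fixed before the data were examined. They cover ribosome biogenesis, translation, stress, proliferation, intestinal identity, cell shape and adhesion, other cell types and RNA quality, and 38 had enough tested members. The result of 1 of these lists and of some named genes is not reported here. Each was also tested with an estimated correlation and with fry. With 1 residual degree of freedom the estimated correlation is itself poorly determined. List medians were computed also with genes at 0 in a group set to their floor, which moved none of the 38.

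The rule for named genes was fixed before the data were examined. It takes FBL, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among genes with adjusted p under 0.05, at least 5 CPM in the mean of the higher group and no overlap between the groups' libraries, and up to 4 members of each list with the smallest p. For a group at 0 counts, fold changes are lower bounds against a floor of 3 counts per library. For a group with 1 to 3 counts the ratio is given with an exact 95% Poisson interval. Floors and intervals cover counting error only.

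Many genes with high counts in siLacZ were at or near 0 in both siFBL tables, in runs of neighbouring genes. A gene was called lost when it had at least 50 counts in siLacZ and was more than 8-fold lower in each siFBL library. Lost genes and 250 kb on either side were joined into stretches. After seeing this, a second fit was made without genes in or near these stretches, and its values stand beside the main ones. It was chosen after the data were seen, as was a fit with both siLacZ tables as separate libraries.

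Alternatives fixed in advance were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no filter beyond 1 count in any library, a filter of at least 1 CPM in at least 2 libraries, a fit that is not robust, and leaving out each table in turn. Without one siFBL library no residual degree of freedom is left, so only the value is given. The test was run on 5 sets of simulated counts for the comparison outside the lost stretches, with about 15380 genes and 200 changed ones. It recovered 69% of 2-fold and 99.8% of 4-fold changes, and 6.12% of its calls were false. Camera found a list of 40 genes shifted by 0.5 on the log2 scale in 5 of 5 sets and an unshifted list in 0. Each gene was simulated at the dispersion of the genes' trend, in siLacZ as in siFBL. These rates therefore do not cover genes that vary more than the trend, or a siLacZ library that does. Counts were simulated independently for each gene. The simulation therefore does not show how often camera passes an unshifted list whose members vary together.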

Results

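The effect of FBL depletion was measured in DLD-1 cells, a colorectal adenocarcinoma line, in a series concerned with cell morphology. FBL encodes fibrillarin, the methyltransferase of the box C/D small nucleolar ribonucleoproteins that methylate ribosomal RNA. The comparison asked which genes differed 72 h after transfection with siFBL from the siLacZ control. There were 2 tables per group, but the siLacZ tables differed by less than the sampling noise and were counted as 1 sample. The comparison thus set 1 siLacZ library (tables of 20635674 and 20631862 counts) against 2 siFBL libraries, siFBL 13 with 16712693 and siFBL 15 with 20169388 counts. The siLacZ library has no replicate, and tests assume that it varied like the siFBL pair. Mitochondrially encoded genes took 5.79% of counts in siLacZ, 4.17% in siFBL 13 and 5.11% in siFBL 15. Small RNA of RNA polymerase III (RN7SL, RN7SK, RMRP and RPPH1) took 7.07% in siLacZ, 9.62% in siFBL 13 and 11.1% in siFBL 15. The share of MALAT1, a nuclear RNA, was 0.508% in siLacZ, 0.758% in siFBL 13 and 1.25% in siFBL 15.

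FBL (gene 2091, chromosome 19, 39834458 to 39846379, GRCh38) had 193 CPM in siLacZ and 38.3 and 19.7 in siFBL 13 and siFBL 15. The siFBL mean was 29.0 ± 13.1 (SD, n = 2). The log2 fold change was -2.74 ± 0.44 (SE). FBL was lower in both siFBL libraries, but in edgeR's quasi-likelihood test its adjusted p was 0.0661, which misses the threshold (unadjusted p = 0.00596). The call depended on the test: the adjusted p was 0.0114 with DESeq2, 0.000203 with limma-voom and 0.0368 with RLE scaling, and over all alternatives it ran from 5.90e-05 to 0.142.

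Among 16554 tested genes, 482 were higher and 792 lower in siFBL in edgeR's quasi-likelihood test, and 3624 had an unadjusted p under 0.05. The falls were divided into 2 kinds by position. Of the 792 lower genes, 465 (58.7%) lay in, or within 250 kb of, 71 places where genes were near 0 in both siFBL libraries. In 41 of these places 2 or more genes were. Genes in or near the places made up 5.61% of those tested. The share of 58.7% is partly by construction, since it includes the lost genes (361, all tested) from which the places were built. Without the genes in those stretches, a fit chosen after the data were seen, 350 genes were higher and 232 lower among 15634 tested. All 582 had also passed with those genes included. Of the 482 rises 14 lay in or near the stretches, so most of the rises that no longer passed lay outside them. The adjustment runs over all tested genes, so taking out many genes with small p raises the adjusted p of others. For KRT13 the unadjusted p in edgeR's test was 0.00182 with the stretches and 0.00112 without them. Its adjusted p was 0.0295 with them and 0.0393 without. With a filter of at least 1 CPM in 2 libraries 279 were higher and 224 lower, and without a filter 919 and 1263.

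The genes with the largest rises included the keratin genes KRT4 and KRT13. KRT4 (chromosome 12, 52806549 to 52814116), a keratin of mucosal epithelium, had 0 counts in siLacZ and 236 and 248 in siFBL, at least 89.2-fold higher (edgeR adjusted p = 1.14e-06). KRT13, the keratin it pairs with, had 1 count in siLacZ and 52 and 163 in siFBL, a ratio of 115 (95% interval 20.6 to 4534 by counting error). CPA4, a carboxypeptidase, had 2 counts in siLacZ and 188 and 114 in siFBL, a ratio of 85.0 (23.5 to 702). SCEL, which encodes the cornified envelope precursor sciellin, had 55 counts in siLacZ and 413 and 474 in siFBL, a log2 fold change of 3.15 ± 0.27 (SE). EMP1, an epithelial membrane protein gene, rose by 3.34 ± 0.25 and CD177, a surface glycoprotein gene, by 4.11 ± 0.31. SLC9C1, VSIR, HMCN2, PID1, WWC2 and RELB completed the 12, with log2 fold changes of 4.27, 3.44, 3.11, 2.95, 2.70 and 2.68. All 12 passed in the fit without the lost stretches too.

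The 12 largest falls all lay in the lost stretches. As given further below, the losses there followed position, and they are not read here as effects of FBL depletion. TUBB, a beta-tubulin gene (chromosome 6, 30720352 to 30725422), had 24826 counts in siLacZ and 0 in both siFBL libraries, at least 7473-fold lower. RPS18, a ribosomal protein gene on chromosome 6, had 14441 counts in siLacZ and 0 in both siFBL libraries, at least 4347-fold lower. PRPF8, a core spliceosome gene on chromosome 17, had 18539 counts in siLacZ and 1 in each siFBL library, a ratio of 16822 (95% interval 4657 to 138903 by counting error). DLG5, PPP1R10, DDR1, ABCF1, MYO19, HSPA1B, CHCHD10, SLC39A7 and SMARCB1 had 0 in both siFBL libraries. In all, 361 genes were lost in this sense, 150 of them at 0 in both siFBL libraries, among 12871 with at least 50 siLacZ counts. Between 28.5 and 33.5 Mb of chromosome 6, which holds the major histocompatibility complex, all 116 genes with at least 50 siLacZ counts were lost. Their counts summed to 171198 in siLacZ, 556 in siFBL 13 and 777 in siFBL 15. Other stretches ran from ZNHIT3 to CWC25 on chromosome 17 (36.49 to 38.83 Mb, 26 of 27 genes lost) and from PARN to NOMO3 on chromosome 16 (14.44 to 16.29 Mb, 15 of 15). Another ran from NDUFA3 to LENG9 on chromosome 19 (54.1 to 54.46 Mb, 13 of 13).

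**Figure D1:**
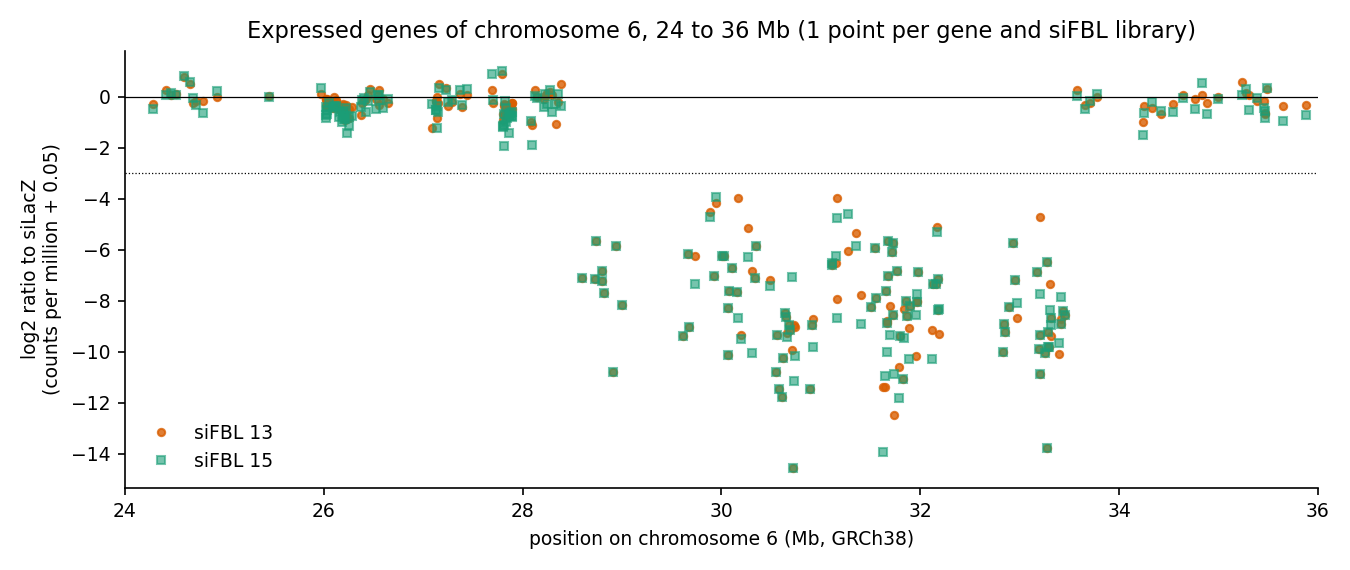
Log2 ratio of each siFBL library to siLacZ (CPM plus 0.05) for the 231 genes with at least 50 siLacZ counts on chromosome 6 between 24 and 36 Mb, by position, with 1 point per gene and library and a dotted line at -3. The 116 lost genes lie from 28.57 to 33.46 Mb with no other expressed gene among them, and the lowest of the 115 genes on either side lies at -1.94.

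Outside the stretches the falls were smaller. That is partly by construction, since a fall of more than 8-fold in each siFBL library from at least 50 siLacZ counts defines a lost gene. The 12 largest falls outside the stretches were taken by the same rule, but after the values had been seen. RPH3AL, a Rab3A effector-like gene, had a log2 fold change of -3.25 ± 0.27 (SE), PCMTD2 -2.78 ± 0.20 and METRNL, which encodes a secreted meteorin-like factor, -2.56 ± 0.27, each passing edgeR's test. APLN, the apelin peptide gene, fell by 2.38, from 5.28 to 0.997 ± 0.299 CPM (SD, n = 2). QTGAL, SLC45A2, MARCHF8, CCDC92, SNORD14D, DNAH10, ADI1 and HERC2 had log2 fold changes from -2.18 to -1.87, and SNORD14D did not pass with DESeq2 (-2.01, adjusted p = 0.0758). RPH3AL lies 0.644 Mb and HERC2 0.332 Mb from a lost gene, and QTGAL and METRNL are neighbours on chromosome 17, as are CCDC92 and DNAH10 on chromosome 12. RPH3AL, SLC45A2, SNORD14D and ADI1 each had 1 other gene within 250 kb that passed as lower, of 3, 3, 7 and 6 tested. PCMTD2, APLN and MARCHF8 had 0 of 3 each, and HERC2 had 0 tested neighbours. Whether some of these falls share a cause with the lost stretches was not tested.

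Of the 38 gene lists tested, 18 passed camera, 28 with limma-voom and 30 without the lost stretches, but 0 with an estimated correlation and 0 with fry. The estimated correlation rests on the difference between the 2 siFBL libraries alone. It came to 1 for heat shock and DNA replication genes, among others, so failing that test decides little for such lists. Adjustment also gave lists with unlike p the same value of 0.922. By that test the unadjusted p was 0.0714 for ribosomal proteins and 0.728 for box H/ACA proteins. Genes of cell shape and adhesion that passed were mostly higher. Of 19 tested desmosome and keratin genes, 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 1.08. KRT80 rose from 41.6 to 120 and 135 CPM, KRT7 by 1.88 ± 0.32 (SE) and KRT8, a main keratin of simple epithelia, by 1.26 ± 0.24. Of 43 integrin, focal adhesion and matrix genes, 10 rose and 0 fell (21 and 1 adjusted over the list alone). The integrin subunit gene ITGB8 rose by 2.01 ± 0.20, the laminin genes LAMB3 and LAMC1 by 1.75 ± 0.18 and 1.29 ± 0.19, and THBS1, encoding thrombospondin, by 1.16 ± 0.18. Of 24 target genes of YAP and TEAD, 9 rose and 0 fell (12 and 1 adjusted over the list alone), among them CCN2 (2.07 ± 0.32), BIRC3 (2.64 ± 0.34), AMOTL2 (1.03 ± 0.19) and MYOF (0.90 ± 0.18). BIRC3 also stands on the NF-kB and apoptosis lists given below, so the rises of these lists are not independent. Of 18 epithelial regulators, 1 rose, ELF3, a transcription factor gene, by 1.75 ± 0.23 (4 rose adjusted over the list alone). Without the lost stretches 10, 9, 8 and 1 members rose (12, 20, 12 and 6 adjusted over the list alone). These 4 lists were higher as groups by camera, with adjusted p of 3.79e-07, 0.000208, 0.000274 and 0.0123 in that order. None held with an estimated correlation (adjusted p = 0.922 for each).

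**Figure D2:**
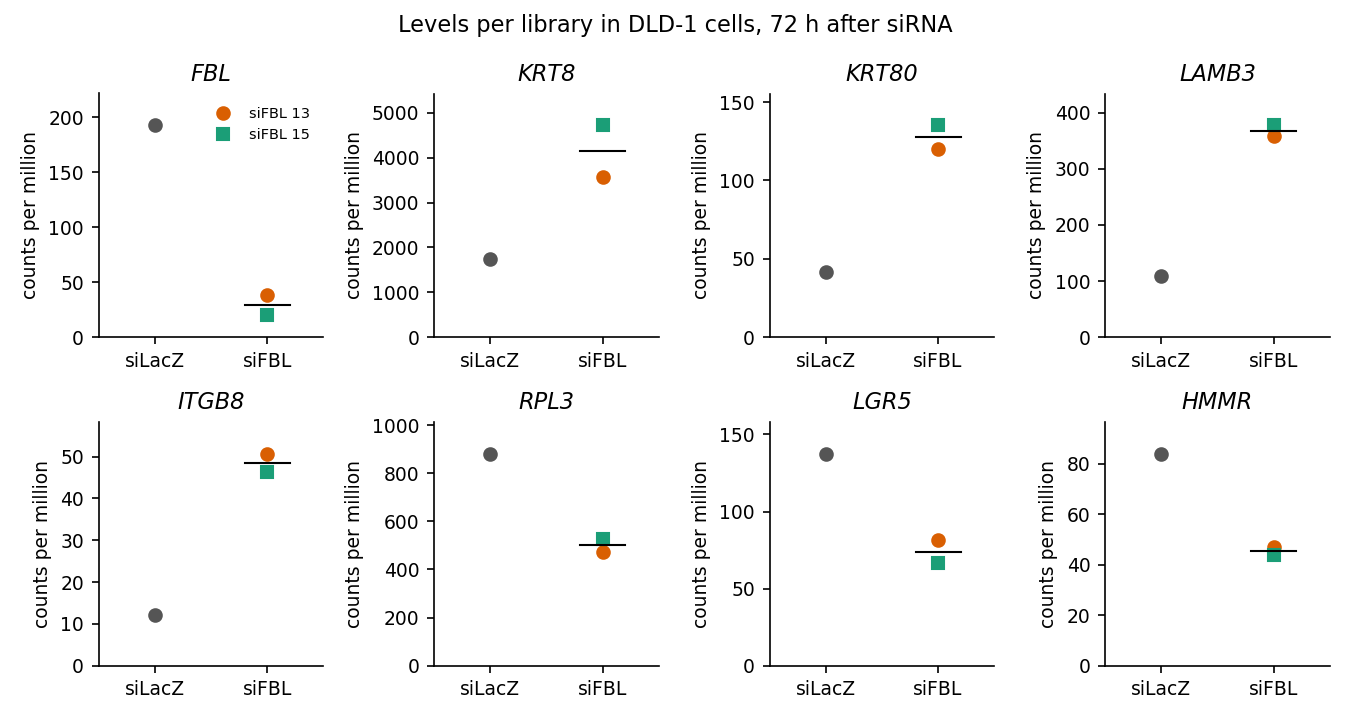
CPM after TMM scaling of 8 genes in the siLacZ library (grey) and in siFBL 13 (circles) and siFBL 15 (squares), with a bar at the siFBL mean. FBL, RPL3, LGR5 and HMMR lie lower and KRT8, KRT80, LAMB3 and ITGB8 higher in both siFBL libraries, and only FBL misses an adjusted p of 0.05.

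Junction genes went both ways. Of 35 adherens and tight junction genes, 5 rose and 4 fell (6 and 5 adjusted over the list alone). CDH1, encoding E-cadherin, rose by 0.89 ± 0.19 (SE) and CGN, encoding cingulin, by 1.09 ± 0.18, whereas TJP1 and MARVELD2 fell and lie in lost stretches. Without the stretches 4 of 32 rose and 0 fell (6 and 2 adjusted over the list alone). The list's median was 0.21 and its mean -0.17, and camera gave an adjusted p of 0.888. Of 31 tubulin and microtubule genes, 1 rose and 7 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.000862), 4 of the tested members lying in or near lost stretches. With an estimated correlation the adjusted p was 0.922. Without the stretches 1 of 27 rose and 3 fell (1 and 5 adjusted over the list alone), and TUBA4A, outside them, fell by 1.59 ± 0.18. The list's mean log2 fold change was -0.90 with the stretches and -0.17 without them, where the camera adjusted p was 0.0282. Of 22 mesenchymal genes, 3 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.231). THBS1 and ITGAV were among those that rose, and SNAI1, encoding a repressor of E-cadherin, fell by 1.44 ± 0.34 but did not pass with DESeq2 (adjusted p = 0.249).

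Genes of ribosome production and translation lay lower. Of 79 ribosomal protein genes, 14 fell and 0 rose (33 and 0 adjusted over the list alone), and 78 had a negative log2 fold change, with a median of -0.39 (camera adjusted p = 1.04e-09). In the fit without the lost stretches, where RPS18 and RPS9, among others, are absent, 9 of 71 fell (26 adjusted over the list alone) and the median was -0.37. There RPL41 fell by 1.16 ± 0.17 (SE) and RPL3 from 920 to 491 and 549 CPM. Of 24 non-coding snoRNA host genes 5 fell (8 adjusted over the list alone, camera adjusted p = 0.00614), among them SNHG3 by 0.89 ± 0.18 and SNHG16 by 0.83 ± 0.17. Of 41 translation factors 3 fell (3 adjusted over the list alone, camera adjusted p = 0.0161), namely EEF1D, in a lost stretch, PABPC4 and EIF3F. Of 44 factors of the small subunit processome 4 fell (4 adjusted over the list alone, camera adjusted p = 0.0144), with UTP4 at -1.73 ± 0.25, TBL3 at -0.75 ± 0.18, UTP20 at -0.73 ± 0.20 and WDR46 in a lost stretch. RNA polymerase I genes passed as a group (camera adjusted p = 0.00155) with 2 of 18 lower (6 adjusted over the list alone), RRN3 and POLR1H, both in lost stretches. Box C/D ribonucleoprotein genes did so too (0.0186), with 1 of 14 lower (2 adjusted over the list alone), ZNHIT3, in a lost stretch. The box C/D list includes FBL, the siRNA target, and was not tested without it. Each of these 6 lists had an adjusted p of 0.922 with an estimated correlation. Outside the lost stretches 3 of 21 snoRNA host genes, 2 of 39 translation factors, 2 of 42 processome factors and 0 RNA polymerase I or box C/D genes passed edgeR's test as lower (7, 2, 3, 0 and 1 adjusted over the list alone, the last being FBL itself). As groups the RNA polymerase I and box C/D lists, the latter with FBL, still passed camera there (adjusted p = 0.00259 and 0.0027). With an estimated correlation neither did (adjusted p = 0.643 for each). UTP20 kept its fold there (-0.73 ± 0.19) but not its call (adjusted p = 0.0686), and lost it too with RLE scaling (0.0607), DESeq2 (0.0510) and limma-voom (0.0612). TBL3 missed the threshold with DESeq2 (-0.74, 0.0521). Large subunit factors (1 of 48 fell, RRP1, but not without the lost stretches, 0 adjusted over the list alone, camera adjusted p = 0.104), box H/ACA proteins (0 of 6 in edgeR, DESeq2 or limma-voom and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05, 0.351) and other RNA modification enzymes (1 of 25 fell, MRM1, in a lost stretch, and 1 adjusted over the list alone, 0.0726) did not pass as groups.

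Proliferation genes were lower by modest amounts. Of 43 genes of G2 and mitosis, 7 fell (24 adjusted over the list alone, median -0.51, camera adjusted p = 0.000374), with HMMR at -0.89 ± 0.17 (SE), KIF20A at -0.78 ± 0.19 and AURKA, a mitotic kinase gene, at -0.76 ± 0.19. Of 41 genes of DNA replication, 3 fell (19 adjusted over the list alone, median -0.57, camera adjusted p = 0.00084), RRM2 by 0.99 ± 0.22, POLD1 by 0.79 ± 0.19 and PCNA by 0.64 ± 0.18. Of 45 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 8 fell (19 adjusted over the list alone, camera adjusted p = 0.00044), H2BC9 by 1.00 ± 0.17. Of 23 genes of nucleotide synthesis, 3 fell (9 adjusted over the list alone, camera adjusted p = 0.027), CAD, RRM2 and PFAS. Of 23 WNT target genes, 8 fell (1 rose and 12 fell adjusted over the list alone, camera adjusted p = 0.0214), among them the intestinal stem cell genes LGR5 (-0.89 ± 0.18) and ASCL2 (-1.06 ± 0.17). With an estimated correlation the adjusted p of each of these 5 lists was 0.922. Without the lost stretches 2, 1, 5, 3 and 7 members fell (23, 22, 22, 8 and 12 adjusted over the list alone). AURKA (-0.77, adjusted p = 0.0547), POLD1 (-0.80, 0.0503) and PCNA (-0.65, 0.0688) kept their folds there and no longer passed.

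Some heat shock and sterol genes fell as well. Of 18 heat shock genes 10 fell (15 adjusted over the list alone, median -0.71, camera adjusted p = 3.79e-07), and 4 of 16 without the lost stretches (13 adjusted over the list alone). BAG3 fell by 0.85 ± 0.17 (SE) and FKBP4 by 0.90 ± 0.18. Of 26 genes of cholesterol synthesis 6 fell (10 adjusted over the list alone, camera adjusted p = 0.00283), with MVK, encoding mevalonate kinase, at -0.80 ± 0.20 and LSS in a lost stretch. Outside the lost stretches 2 of 23 fell (10 adjusted over the list alone), and MVK no longer passed (-0.80, adjusted p = 0.0527). For each of the 2 lists the adjusted p was 0.922 with an estimated correlation. Of 22 chaperones of the unfolded protein response 4 fell (8 adjusted over the list alone, camera adjusted p = 0.0587), among them CALR, encoding calreticulin, by 0.80 ± 0.17, and 2 of 21 without the lost stretches (7 adjusted over the list alone).

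**Figure D3:**
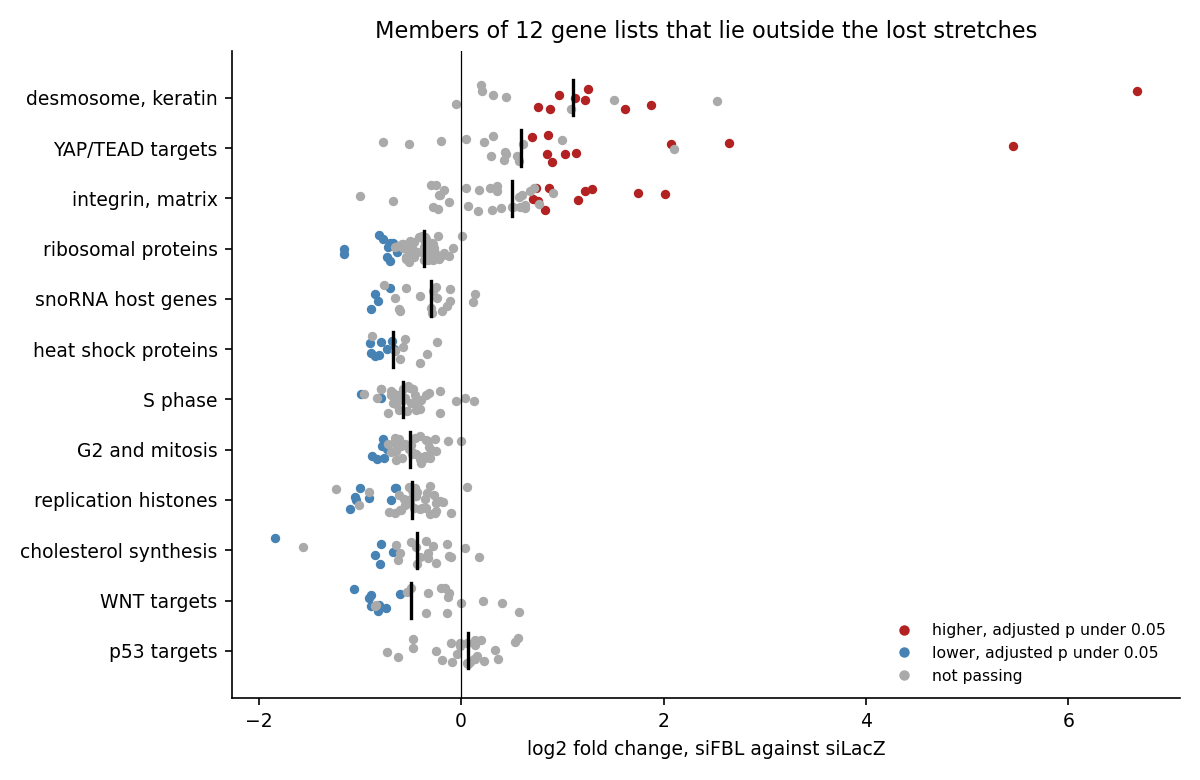
Log2 fold changes (siFBL against siLacZ, x axis) of the members of 12 gene lists that lie outside the lost stretches, coloured by edgeR's test, with a bar at each median. KRT4, at 0 counts in siLacZ, enters the median but is not drawn. Desmosome and keratin, YAP/TEAD and integrin genes lie to the right and ribosomal, proliferation and heat shock genes to the left, while p53 targets spread around 0.

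The remaining lists did not pass as groups in the main comparison. Of 31 inflammatory NF-kB genes, 4 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.114). RELB and NFKB2, encoding NF-kB subunits, rose by 2.68 ± 0.36 (SE) and 1.30 ± 0.22. Of 29 immediate early genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone, 0.119), with DUSP5 at 2.16 ± 0.29, JUNB at 1.19 ± 0.21 and EGR1 at 1.08 ± 0.21. Enterocyte genes numbered 3 higher and 2 lower of 21 (8 and 2 adjusted over the list alone, 0.0969), with CEACAM6 at 2.21 ± 0.30 and LGALS4 at 1.67 ± 0.32. Secretory cell genes numbered 1 higher and 4 lower of 14 (3 and 6 adjusted over the list alone, 0.442). REG4 rose by 2.52 ± 0.23, and MUC2 and DLL1 fell in lost stretches. Without the stretches the falls numbered 0 among NF-kB and immediate early genes and 1 each among enterocyte and secretory genes, with the rises at 4, 5, 3 and 1 (falls 0, 1, 1 and 2 and rises 6, 5, 7 and 3 adjusted over the list alone). Apoptosis regulators numbered 3 higher and 0 lower of 30 (4 and 1 adjusted over the list alone, 0.104), and hypoxia and glycolysis genes 0 higher and 5 lower of 34 (0 and 5 adjusted over the list alone, 0.204), LDHA by 0.68 ± 0.17. Outside the lost stretches 1 of 28 apoptosis regulators, BIRC3, rose and 1 of 33 hypoxia and glycolysis genes fell (4 rises and 1 fall, and 4 falls, adjusted over the list alone). LDHA no longer passed there (-0.69, adjusted p = 0.058). Without the lost stretches 12 further lists passed camera. Inflammatory (adjusted p = 1.53e-05), immediate early (9.22e-05), enterocyte (0.000157), secretory (0.0481), apoptosis (0.0391) and junction genes (0.00364) did so as higher, though 27 of the 31 inflammatory genes had more CPM in siFBL 13 than in siFBL 15. Large subunit factors (4.91e-05), box H/ACA proteins (0.0238), RNA modification enzymes (0.0047), unfolded protein response (0.000287), hypoxia (0.00303) and mitochondrially encoded genes (0.000576) did so as lower. With an estimated correlation none of the 12 held (adjusted p = 0.643 to 0.68). Interferon genes numbered 1 higher and 1 lower of 31 (2 and 1 adjusted over the list alone, 0.508), with a median of 0.22 and a mean of -0.01, and none passed without the lost stretches, where the mean was 0.21.

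No p53 target passed among 26, over all genes or adjusted over the list alone (camera adjusted p = 0.844), and none did with DESeq2 or limma-voom. In edgeR 3 had an unadjusted p under 0.05, DDB2 at -0.73 ± 0.24 (SE), BTG2 at -0.63 ± 0.21 and FDXR at -0.48 ± 0.22. Of 33 genes of the integrated stress response 1 fell, CARS1, in a lost stretch (1 adjusted over the list alone, 0.873). The nuclear-encoded respiratory chain had 1 of 52 lower, NDUFA10 (0 adjusted over the list alone, 0.789), and mitochondrially encoded genes 1 of 13 lower, ND3 (1 adjusted over the list alone, 0.131). Neither NDUFA10 (-0.65, adjusted p = 0.0636) nor ND3 (-0.63, 0.0709) passed without the lost stretches. Lysosome and autophagy genes had 1 of 38 lower (1 adjusted over the list alone, 0.651), with a median of 0.13 and a mean of -0.12, and 0 of 36 outside the stretches, where the mean was 0.12. RNA interference genes had 1 of 13 lower, DROSHA (2 adjusted over the list alone, 0.969), with a median of 0.04, a mean of -0.06 and a downward test. Markers of other cell types were scarce. Of 15 fibroblast and 17 leukocyte and endothelial markers, 4 each were tested and 1 passed, COL5A2, which rose but did not pass with DESeq2 (adjusted p = 0.112) (1 higher and 1 lower, and 0, adjusted over the list alone). The summed fibroblast markers came to 16.9 CPM in siLacZ and 21.3 and 16.7 in siFBL, and the leukocyte and endothelial markers to 9.16, 10.4 and 11.3.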

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

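Fits without the lost stretches and with both siLacZ tables as separate libraries were chosen after the data were seen. No paired analysis was possible because the siLacZ tables of replicates 13 and 15 hold 1 library. Leaving out either siLacZ table gave 1274 to 1278 genes changed, 482 to 484 higher, 792 to 794 lower, and 18 lists. Leaving out either siFBL library left no residual degree of freedom and hence no counts or list tests. RLE scaling, upper quartile scaling, DESeq2, limma-voom and the fit that is not robust gave between 995 and 1341 changed genes against 1274, each with more falls than rises. With no filter there were 2182 (919 higher, 1263 lower). With at least 1 CPM in 2 libraries there were 503 (279 higher, 224 lower). That filter removes genes absent from both siFBL libraries, and without their small p the adjustment is stricter for the genes that remain. How much of the drop in rises this accounts for was not tested. Without the lost stretches there were 582 (350 higher, 232 lower). With both siLacZ tables as separate libraries there were 4475 (2188 higher, 2287 lower), but there 1 library stands as 2, so that spread is not one between samples. Single genes went either way, and KRT13 no longer passed (adjusted p = 0.0538).

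Camera passed 18 lists, 28 with limma-voom, 30 without the lost stretches and 30 with both siLacZ tables. With an estimated correlation 0 passed, with 0 at an unadjusted p under 0.05 (smallest 0.0714), and with fry 0 passed, with 2 at an unadjusted p under 0.05. The 18 lists passed under each other alternative that was run. Secretory intestinal genes leaned lower in the main fit and passed as higher without the lost stretches (adjusted p = 0.0481), where 4 members are absent. The fall of FBL kept its direction under every alternative run, from -3.29 to -2.33 when one library was left out. It passed with RLE scaling (-2.74, adjusted p = 0.0368), the fit that is not robust (-2.74, 5.90e-05), DESeq2 (-2.73, 0.0114), limma-voom (-2.82, 0.000203) and both siLacZ tables (-2.73, 0.0332). In the other fits the adjusted p ran from 0.0549 to 0.142. Where no construction is named, the cause was not tested. None of 218 other genes, the named ones and the leading list members, changed sign under an alternative in which they were tested. With one siFBL library left out, none of the 154 that had passed changed sign. Sign changes among the genes that had not passed were not counted there. Of the 154 that passed, 119 passed under each alternative fixed in advance in which they were tested, and 35 lost the call under at least 1. Depth limits the folds of genes at 0, where up to 3 counts cannot be excluded.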

Other observations

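Tests on the lost stretches and on the siFBL pair were chosen after the results were seen. Those on snoRNA and squamous genes were chosen after single genes (SNORD14D, and KRT4, KRT13 and SCEL) had been seen among the changed ones, with the deciding bounds set before the tests were run.

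The siFBL libraries differed from one another in inflammatory genes. LCN2, encoding an antimicrobial siderophore-binding protein, had 114 counts in siLacZ, 3039 in siFBL 13 and 280 in siFBL 15. The chemokine genes CXCL8 and CCL20 had 256 and 122 counts in siFBL 13 and 19 and 1 in siFBL 15, against 11 and 0 in siLacZ. SAA1 had 144 counts in siFBL 13 and 2 in both other libraries. IL33 went the other way, with 475 counts in siFBL 13 and 1558 in siFBL 15. None of these passed edgeR's test between siFBL and siLacZ. Of 31 tested NF-kB genes, 27 were higher in siFBL 13 than in siFBL 15. RELB and BIRC3 were high in both siFBL libraries, as reported. Leukocyte RNA in siFBL 13 is argued against by the summed leukocyte and endothelial markers, at 0.92 times the siFBL 15 level. Library size is argued against too, since the 27 of 31 were counted in CPM, which are scaled for it. The list's median raw count ratio of siFBL 13 to siFBL 15 was 1.24 and that of all tested genes 0.881. These ratios restate the CPM difference and are no separate test. A difference between the transfected cultures stays open and was not tested.

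The near-complete loss of 361 genes in both siFBL libraries followed position. Of those with a position, 89.3% had another lost gene within 250 kb, against at most 25.7% in 1000 random draws of genes with similar counts. This argues against a position-independent loss of transcripts after FBL depletion as the cause. Deletion of the stretches is argued against by 3 ribosomal protein genes among the lost, RPS9 and RPS18 among them, which cells cannot do without. A candidate explanation is that reads of these stretches were left uncounted in the siFBL tables, for example because siFBL reads were matched to a reference with alternate versions of these regions and siLacZ reads were not. The grouping by position raised this explanation and so lends it no further weight. It stays open, since both siFBL libraries and not siLacZ are affected, and the reads that would decide it were not analysed here. A difference in processing between the siFBL and siLacZ tables would coincide with the treatment for every gene, not only the lost ones. It could not be told apart from an effect of FBL depletion.

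Box C/D snoRNA, the class that fibrillarin binds, was hypothesised to fall with it. Outside the lost stretches, 112 of 123 tested box C/D genes (SNORD) had a negative log2 fold change, with a median of -0.73, and 47 of 79 box H/ACA genes (SNORA), with a median of -0.12. The difference of medians was -0.61 (2-sided permutation test over genes, 100000 resamples, p = 1e-05, the smallest they can give). It was seen in each siFBL library, where the C/D medians were -0.57 in siFBL 13 and -0.84 in siFBL 15 and the H/ACA medians 0.03 and -0.20. Most snoRNA lie in introns of other genes, many of which had lower counts too. After subtracting the log2 fold change of the gene that spans each snoRNA, for 115 C/D and 78 H/ACA genes, the medians were -0.25 and 0.17 and the difference was still -0.42 (permutation test, p = 1e-05), which argues against the fall of these genes as the whole cause. Single members had few counts, with a median of 34 in siLacZ, and 4 C/D genes passed edgeR's test, SNORD14D, SNORD14E, SNORD32A and SNORD13, which were named after their values were seen, and SNORD14D did not pass with DESeq2. The hypothesis that box C/D snoRNA may be lost with their core protein thus remains open, with members that share host genes and 1 siLacZ library. The labels name polyA RNA, but histone genes whose transcripts mostly lack a poly(A) tail summed to 10582 CPM in siLacZ, before TMM scaling. How fully these libraries hold snoRNA is therefore not known.

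A wider squamous programme was hypothesised from KRT4, KRT13 and SCEL. A list of 46 squamous genes that leaves out those already seen had 19 tested members, of which 2 rose, GPRC5A by 1.49 ± 0.19 (SE) and TRIM29 by 1.58 ± 0.24. The median log2 fold change was 0.021 (95% bootstrap interval -0.12 to 0.84, 10000 resamples) over members that went both ways. Camera gave p = 0.015 with the preset correlation, and with an estimated correlation p = 0.485. A median below 0.2 had been set beforehand to count against the hypothesis, and the median lay below it. An adjusted camera p under 0.05 with a positive median had been set to count for it. With the preset correlation and no other list to adjust over, that held too. The rules set beforehand thus conflict. The bootstrap interval, which was not part of them, reaches above 0.2, and the question was left open.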
